A study of Homo sapiens with 6 samples.

How the data were processed

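RNA sequencing was carried out on 6 libraries of the MV4-11 leukaemia line, 3 described as untreated and 3 as carrying an ENO1 knockdown. Per the labels' protocols, RNA was taken up in Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. Per the submitters' processing notes, HISAT2 2.0.5 and the genome build hg38 were used. The read counter, the gene annotation and the strand setting are not given in the sources used here. The values are whole-number counts of reads per Ensembl gene, not normalized, as the authors deposited them in 1 table with 1 column per library, per the file headers. The column names of the knockdown libraries carry the name of 1 hairpin, and each column was matched to a sample by the group and replicate number in its name. Samples were grouped by their titles. The labels describe the controls as untreated, while their titles and columns carry the letters NC, which are not spelled out, and whether they carried a control hairpin is not given.

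The table held 23227 genes, of which 23211 carried a symbol and 16 did not. The lowest sum of a gene over the 6 libraries was 2, so genes at 0 in all libraries were not among them. Library totals ran from 20044602 to 26373960 counts. Gene positions, exon overlap, GC content and transcript length came from GENCODE release 29 on GRCh38, which is the build the submitters name as hg38. GC content and length were found for 14056 of the 14635 tested genes (96.0%). For each gene named with a value of its own, the share of its 50-base stretches that also occurred in transcripts of other genes was computed, and genes with more than 10% are given as uncertain.

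Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr at its default settings and the robust quasi-likelihood fit and test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 14635 genes, which held 99.91% of the counts, and removed 8592. The common biological coefficient of variation was 0.0392. Levels are given as CPM on TMM-scaled library sizes. Standard errors are approximate, taken as the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 2.10 to 4.20, against 71.0 to 76.4 between libraries of different groups, and none were identical. Intervals on counts are exact Poisson intervals at 95% and cover counting error only.

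Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists that had at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in one direction and does not compare the list with other genes.

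The 35 lists, the design, the main alternatives and the rule for named genes were chosen before the data were examined. The rule named ENO1, ENO2 and ENO3, the 10 highest and the 10 lowest log2 fold changes among genes with a symbol that passed the test, had a mean of at least 10 CPM in the higher group and had all libraries of one group above all of the other, and up to 4 members of each list with the smallest adjusted p. Some list examples are left out of the text, and some items are not reported here. Members that moved against the rest of their list were named after their values were seen.

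The alternatives were RLE, upper-quartile and plain library-size scaling, no filter, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a threshold of 0.01 and an added 2-fold threshold. A correction for GC content and length by smooth trends (mgcv 1.9.3), thinning to the smallest library and setting aside the 2 libraries that stood apart were added after the data were seen. A further 4 lists (mitochondrially encoded mRNAs, replication-dependent histones, LXR targets and interferon genes) were also added then.

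The procedure was tested on simulated data for the comparison of knockdown and control, with counts drawn for the 14635 genes from the means and library sizes of these libraries. Of the genes changed 1.2-fold, 23 of 50 (46.0%) were recovered with the right sign, 33 of 49 (67.3%) of those changed 1.5-fold, 43 of 46 (93.5%) of those changed 2-fold and 47 of 49 (95.9%) of those changed 4-fold. Of 14235 unchanged genes, 13 were called. Only a small part of the genes was changed in the simulation, while 59.9% were called in the data. The Benjamini-Hochberg adjustment was therefore stricter in the simulation, and the recovered shares may be lower than those in the data. A list shifted 1.5-fold was called by camera with the preset correlation but not with an estimated correlation, and 0 of 29 unshifted lists were called. The simulated lists held random genes drawn independently, so they cannot show how often lists of correlated genes would be falsely called. A simulated GC trend gave 3339 false calls without the correction and 13 with it. Python 3.11.15 and matplotlib 3.10.9 were used for the figures.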

Results

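Gene expression was measured by RNA sequencing in MV4-11, an established human acute myeloid leukaemia cell line that carries a KMT2A-AFF1 fusion and an internal tandem duplication in FLT3. The series held 6 libraries in 2 groups of 3. The control group was described in the labels as untreated, and the other group as carrying a knockdown of ENO1, the glycolytic enzyme alpha-enolase, which converts phosphoglycerate to phosphoenolpyruvate. The comparison of the groups addressed how the transcriptome of these cells differs with and without the knockdown of ENO1. The control libraries held 26373960, 24989082 and 24778469 counts and the knockdown libraries 21067990, 21670135 and 20044602, in the order of their replicate numbers. Between 19870 and 19883 genes had at least 1 count in a control library, and between 20407 and 20462 in a knockdown library. Mitochondrially encoded genes took 6.71, 6.88 and 6.69% of the counts in the control libraries and 9.27, 9.69 and 9.64% in the knockdown libraries. The first principal component held 76.4% of the variance and separated the groups. Control replicate 2 and knockdown replicate 3 stood somewhat apart from the other libraries of their groups, with a chi-square per degree of freedom of 2.84 and 3.15 for the control and 4.04 and 4.20 for the knockdown library, against 2.10 and 2.29 between the remaining pairs. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

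ENO1 itself (ENSG00000074800, GRCh38 chromosome 1, 8861000 to 8879250, minus strand) was low in every knockdown library. Its counts were 84016, 79566 and 80058 in the controls and 2225, 2225 and 2070 in the knockdown libraries. The mean level fell from 3262 ± 22.6 CPM (SD, n = 3) to 102.1 ± 1.25 CPM (SD, n = 3), which left 3.13% of the control level, a reduction of 96.9%. The log2 fold change was -4.998 with an approximate standard error of 0.03 (edgeR quasi-likelihood adjusted p = 5.98e-37). The paralog ENO2, the neuronal enolase, was expressed at a far lower level. It fell from 10.9 ± 1.14 to 3.71 ± 1.01 CPM (SD, n = 3), a log2 fold change of -1.56 with an approximate standard error of 0.15 (edgeR adjusted p = 7.75e-10). The muscle enolase ENO3 was at 13.7 ± 0.984 CPM in the controls and 12.0 ± 1.19 CPM in the knockdown cells (SD, n = 3) and did not pass the test (edgeR adjusted p = 0.0824). ENO3 passed it when knockdown replicate 2 was left out (edgeR adjusted p = 0.0351).

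The difference between the groups reached most expressed genes. Of 14635 genes tested, 4309 (29.4%) were higher and 4458 (30.5%) were lower in the knockdown cells at an edgeR quasi-likelihood adjusted p below 0.05. Most of these differences were small, with a median size of 0.49 on the log2 scale for the genes that rose and 0.39 for those that fell. At least 2-fold differences were found for 953 of the genes that rose and 521 of those that fell, and at least 4-fold differences for 252 and 90. The libraries of one group lay entirely above those of the other for 9405 genes (64.3%), where chance gives 10%.

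**Figure D1:**
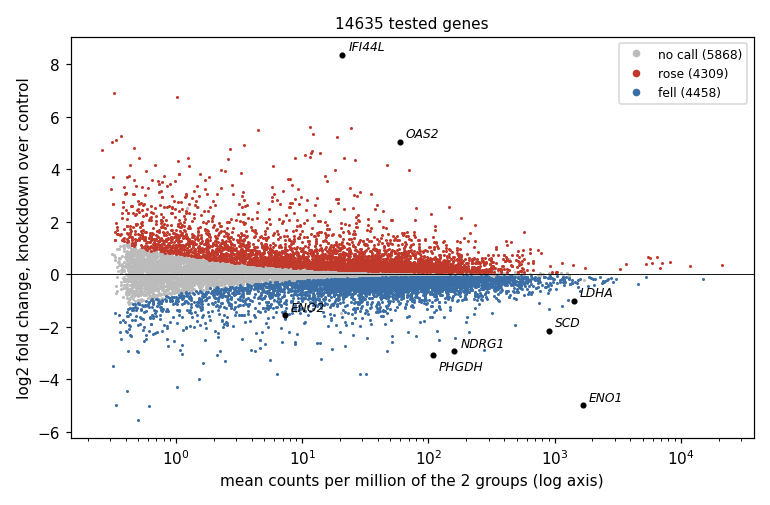
Each point is 1 of the 14635 tested genes, placed by its mean level over the 2 groups (CPM, log axis) and its log2 fold change in the knockdown over the control cells; red points rose and blue points fell at an edgeR adjusted p below 0.05. ENO1 lies at a log2 fold change of -4.998 and IFI44L at 8.36.

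Most of the 10 largest rises were in genes known to be induced by interferon. IFI44L was close to undetected in the controls, with 9 counts over the 3 libraries, and had 2642 counts over the knockdown libraries, a ratio of 343 (95% exact Poisson interval 181 to 751, counting error only). The antiviral oligoadenylate synthetases OAS3 and OAS2 had log2 fold changes of 5.62 and 5.06, and OAS2 rose from 3.44 ± 0.57 to 115 ± 5.56 CPM (SD, n = 3; edgeR adjusted p = 4.36e-27). IFI44 rose by 5.56, IFI27 by 5.36, IFIT1 by 4.70 and the helicase DDX60 by 4.62 on the log2 scale. Genes outside that class were also among the 10 highest: the rhomboid family gene RHBDL3 rose by 5.22, SUCNR1, the receptor for succinate, by 4.62 and the envoplakin gene EVPL by 4.53.

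Among the 10 lowest log2 fold changes, which included that of ENO1, PSTPIP1, a cytoskeletal adaptor of haematopoietic cells, was at -3.81, the myeloid progenitor gene MS4A3 at -3.79, LINC03040 at -3.79 and the myeloid nuclear differentiation antigen MNDA at -3.22. RNASE2, the eosinophil-derived neurotoxin, and the TSPO-binding gene TSPOAP1 had log2 fold changes of -2.94 and -2.88. HSD11B1, which converts cortisone to cortisol, had a log2 fold change of -3.26. PHGDH, the first enzyme of serine synthesis, fell from 194 ± 6.36 to 23.2 ± 0.833 CPM and the hypoxia-responsive NDRG1 from 284 ± 2.93 to 37.1 ± 0.795 CPM (SD, n = 3). The rule that chose the 10 highest and 10 lowest genes required all libraries of one group to lie above all of the other. The largest edgeR adjusted p among these genes was 1.55e-14.

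**Figure D2:**
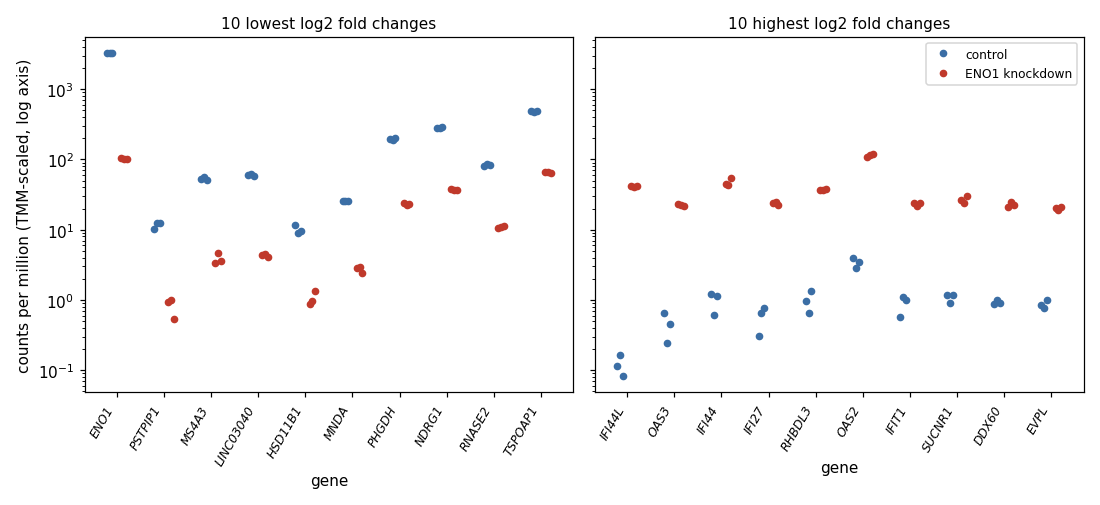
Level in CPM in each of the 6 libraries (log axis) for the 10 genes with the lowest and the 10 with the highest log2 fold change under the fixed rule; blue points are control and red points knockdown libraries. The rule required that the groups not overlap for any of these genes. IFI44L has a mean of 0.121 CPM in the controls against 41.4 CPM in the knockdown libraries.

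Of 35 gene lists, 30 had at least 5 tested members and were tested with camera at a preset correlation of 0.01. In that test 6 lists were higher and 13 lower in the knockdown cells. With an estimated correlation, 4 of the higher and 9 of the lower lists passed. The 6 calls that were lost are given with their p beside each list. The lists that still passed had much larger camera adjusted p with an estimated correlation than with the preset one. These ran from 0.00118 for interferon-stimulated genes to 0.0334 for granulocyte differentiation. Counts of members that rose or fell refer to the adjustment over all genes tested. Adjusted over the list alone, the counts were the same except where another count is given. Members named because they moved against their list, and not under the fixed rule, were chosen after their values were seen.

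**Figure D3:**
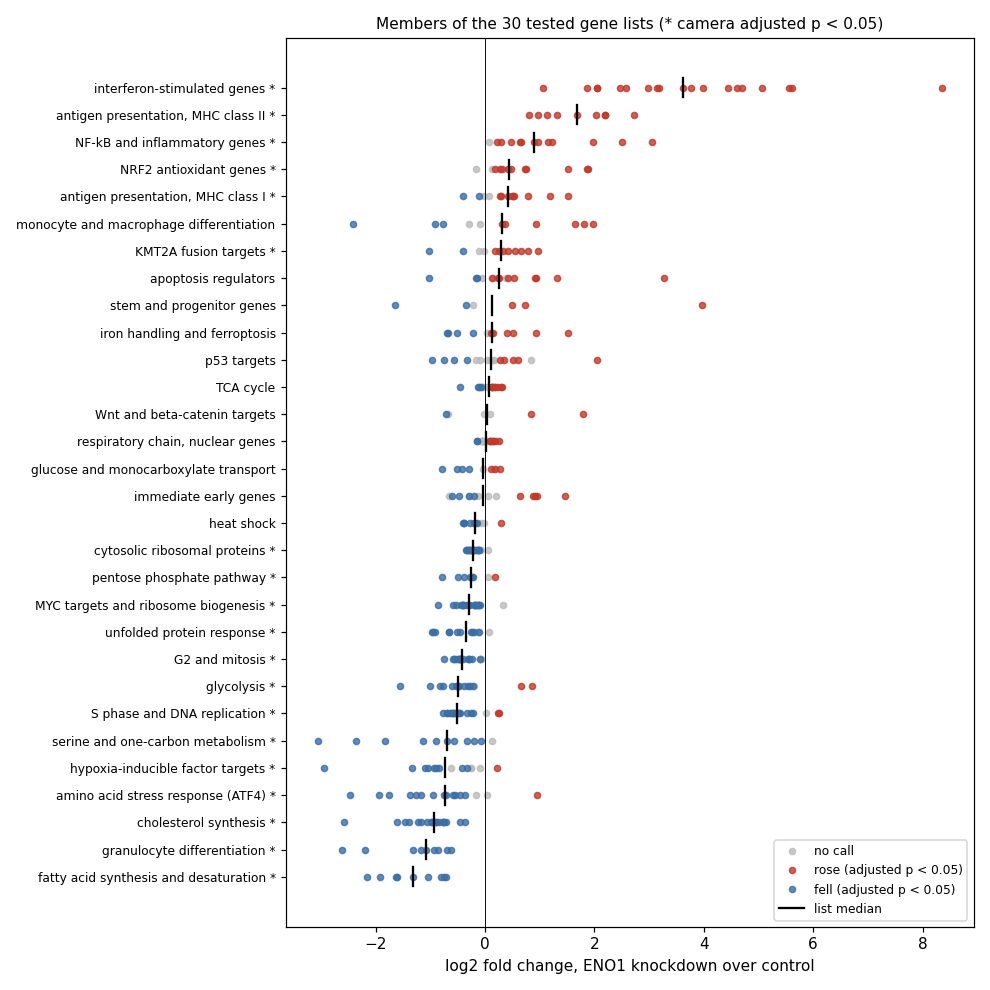
Each row is 1 of the 30 tested gene lists, and each point a member's log2 fold change in the knockdown over the control cells; red points rose, blue points fell and grey points had no call at an edgeR adjusted p below 0.05. Black bars mark list medians, which run from -1.32 for fatty acid synthesis to 3.62 for interferon-stimulated genes, and asterisks mark camera adjusted p below 0.05.

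Genes of lipid synthesis were uniformly lower in the knockdown cells. All 18 genes of cholesterol synthesis and uptake fell, with a median log2 fold change of -0.94 (camera adjusted p = 1.82e-28). The reductase gene DHCR7 fell from 88.8 ± 3.38 to 14.9 ± 1.91 CPM (SD, n = 3), a log2 fold change of -2.58, and SREBF2, the transcription factor that drives the pathway, had a log2 fold change of -0.97. All 9 tested genes of fatty acid synthesis and desaturation fell, with a median of -1.32 (camera adjusted p = 1.97e-35). The desaturase SCD fell from 1463 ± 2.60 to 329 ± 9.84 CPM (SD, n = 3), and FADS2, FADS1 and the elongase ELOVL5 had log2 fold changes of -1.92, -1.61 and -1.62.

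Glycolytic and serine pathway genes also fell. In the glycolysis list, which did not hold ENO1, 13 of 16 genes fell and 2 rose, with a median of -0.49 (camera adjusted p = 1.76e-06). Lactate dehydrogenase LDHA fell from 1899 ± 12.8 to 940 ± 24.4 CPM (SD, n = 3), hexokinase HK2 had a log2 fold change of -0.82 and PGK1 of -0.61. The phosphofructokinases PFKP and PFKM rose, by 0.86 and 0.65 on the log2 scale. PFKL, the phosphofructokinase gene with the highest control level, fell, and was named after its value was seen. Of 11 genes of serine and one-carbon metabolism, 10 fell and none rose, with a median of -0.69 (camera adjusted p = 4.09e-18); adjusted over the list alone, 1 rose. PSAT1 had a log2 fold change of -1.83, SHMT2 of -1.13 and ALDH1L2 of -2.35. In the pentose phosphate pathway 6 of 8 genes fell and 1 rose. Those that fell included PGD at -0.79 and TKT at -0.50. The list median was -0.25 (camera adjusted p = 0.0325; adjusted p = 0.125 with an estimated correlation), and without genes below 5 CPM the list did not pass (camera adjusted p = 0.102).

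Targets of hypoxia-inducible factor fell, 9 of 14 lower and 1 higher, with a median of -0.73 (camera adjusted p = 2.99e-10). Besides NDRG1, examples were the mTOR regulator DDIT4 at -1.33, the pyruvate dehydrogenase kinase PDK1 at -1.04 and the angiogenic factor VEGFA at -0.94. PFKFB3 rose by 0.21. Genes of the amino acid stress response fell, 13 of 16 lower and 1 higher, with a median of -0.73 (camera adjusted p = 3.19e-07). ATF4, the transcription factor of that response, had a log2 fold change of -0.47, the pseudokinase TRIB3 of -1.76, the amino acid transporter SLC7A5 of -0.76 and CEBPB of -1.25, while ATF3 rose by 0.96. Of 14 genes of the unfolded protein response, 11 fell and none rose, with a median of -0.36 (camera adjusted p = 4.98e-06); adjusted over the list alone, 12 fell. The endoplasmic reticulum chaperones HYOU1, HSPA5 and HSP90B1 had log2 fold changes of -0.95, -0.66 and -0.66, and PDIA4 of -0.52.

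Genes of growth and division also fell. In the S phase list 15 of 18 genes fell and 2 rose, with a median of -0.51 (camera adjusted p = 2.92e-07). The replicative helicase genes MCM4 and MCM7 had log2 fold changes of -0.70 and -0.63, and the sliding clamp PCNA of -0.58, while MCM6 and the cyclin CCNE2 rose by 0.25 and 0.24. In the list of G2 and mitosis 15 of 18 genes fell and none rose, with a median of -0.43 (camera adjusted p = 5.05e-06; adjusted p = 0.0682 with an estimated correlation); adjusted over the list alone, 17 fell. CENPF, TPX2, AURKB and the proliferation marker MKI67 had log2 fold changes of -0.76, -0.51, -0.58 and -0.45. MYC fell from 566 ± 7.97 to 313 ± 6.27 CPM (SD, n = 3), and 19 of the 20 genes in the list of MYC targets and ribosome biogenesis fell, with a median of -0.29 (camera adjusted p = 4.28e-05; adjusted p = 0.0575 with an estimated correlation). FBL, NCL and ODC1 had log2 fold changes of -0.59, -0.42 and -0.40. Of 20 cytosolic ribosomal protein genes 17 fell and none rose, with a median of -0.22 (camera adjusted p = 0.0133; adjusted p = 0.506 with an estimated correlation); adjusted over the list alone, 18 fell and 1 rose. RPL4 and RPL5 were both at -0.34. Without genes below 5 CPM this list did not pass (camera adjusted p = 0.0722). Genes whose symbols start with RPL or RPS and a digit together took 6.50, 6.89 and 6.43% of the counts in the control libraries. They took 5.97, 5.76 and 6.07% in the knockdown libraries, while the mitochondrially encoded share was higher in those libraries. That set leaves out ribosomal protein genes such as RPLP0 and RPLP1 and can take in other genes with such symbols.

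All 19 tested interferon-stimulated genes rose, with a median log2 fold change of 3.62 (camera adjusted p = 3.65e-71). OAS1 rose from 1.87 ± 0.43 to 41.0 ± 2.34 CPM (SD, n = 3), by 4.45 on the log2 scale. In the list of NF-kB and inflammatory genes 12 of 13 rose and none fell, with a median of 0.89 (camera adjusted p = 4.98e-06). The ubiquitin-editing enzyme TNFAIP3 rose by 1.22, the adhesion molecule ICAM1 by 0.97, TNF by 0.89 and the chemokine CCL2 by 3.06. All 9 tested genes of MHC class II antigen presentation rose, with a median of 1.68 (camera adjusted p = 1.42e-08). CD74, the invariant chain, rose from 263 ± 1.85 to 575 ± 10.6 CPM (SD, n = 3), HLA-DRA and HLA-DRB1 rose by 2.20 and 2.03, and CIITA, the coactivator of class II genes, by 0.96. In the MHC class I list 9 of 13 genes rose and 2 fell, with a median of 0.41 (camera adjusted p = 0.00132; adjusted p = 0.0901 with an estimated correlation). The peptide transporter TAP1 rose by 1.52, and HLA-B, HLA-C and HLA-E by 0.50, 0.53 and 0.50. NLRC5, the coactivator of class I genes, and TAP2 fell, with log2 fold changes of -0.41 and -0.12.

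All 9 tested genes of granulocyte differentiation fell, with a median of -1.08 (camera adjusted p = 1.86e-10). The receptor for granulocyte colony-stimulating factor, CSF3R, fell from 112 ± 4.18 to 24.6 ± 1.17 CPM (SD, n = 3), and the granule genes MPO, CTSG and AZU1 had log2 fold changes of -2.61, -1.31 and -0.86. In the monocyte and macrophage list 6 of 11 genes rose and 3 fell, and the list did not pass (camera adjusted p = 0.456). Its median of 0.30 and mean of 0.23 were positive while camera and fry gave a downward direction. Lysozyme (LYZ), the receptor FCGR1A and TLR2 had log2 fold changes of -2.41, -0.91 and -0.78, whereas the integrin ITGAM rose by 1.81. Among targets of KMT2A fusions, the class of oncoprotein present in this line, 8 of 12 genes rose and 2 fell, with a median of 0.29 (camera adjusted p = 0.0133; adjusted p = 0.125 with an estimated correlation). JMJD1C, MEIS1 and CDK6 rose by 0.97, 0.79 and 0.55, while the antiapoptotic BCL2 and the transcription factor MYB had log2 fold changes of -1.03 and -0.40. In the stem and progenitor list 3 of 6 genes rose and 2 fell (camera adjusted p = 0.179), and the receptor KIT rose from 0.269 ± 0.0905 to 4.28 ± 0.430 CPM (SD, n = 3).

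Antioxidant targets of NRF2 rose, 10 of 12 higher and none lower, with a median of 0.44 (camera adjusted p = 2.41e-05). NQO1, OSGIN1 and the haem oxygenase HMOX1 rose by 1.86, 1.88 and 1.52, and the peroxiredoxin PRDX1 from 295 ± 10.8 to 494 ± 18.9 CPM (SD, n = 3). In the list of iron handling and ferroptosis 6 of 12 genes rose and 4 fell (camera adjusted p = 0.288), with the transferrin receptor TFRC and the ferritin light chain FTL at 0.93 and 0.41 and ACSL4 at -0.69. Of 15 apoptosis regulators 9 rose and 3 fell (camera adjusted p = 0.103). The proapoptotic BCL2L11 and BMF rose by 0.93 and 0.91, while the proapoptotic BID fell. Antiapoptotic members went both ways, with rises of BCL2L1, XIAP and BIRC3 and falls of BCL2 and MCL1. BID and the antiapoptotic members other than BCL2 were named after their values were seen. Among p53 targets 5 of 16 rose and 4 fell (camera adjusted p = 0.234), with BTG2 at 2.05, RRM2B at 0.51, TNFRSF10B at -0.74 and BAX at -0.34.

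Mitochondrial pathways encoded in the nucleus did not pass as sets. In the TCA cycle list 8 of 16 genes rose and 4 fell (camera adjusted p = 0.572), with fumarase FH at -0.46 and IDH3B at 0.30, and in the list of nuclear respiratory chain genes 6 of 21 rose and 2 fell (camera adjusted p = 0.632); adjusted over the list alone, 5 rose and 2 fell. Of 9 genes of glucose and monocarboxylate transport 3 rose and 4 fell (camera adjusted p = 0.362). In the heat shock list 7 of 10 genes fell and 1 rose, with a median of -0.19 (camera adjusted p = 0.102). Of 14 immediate early genes 5 rose and 4 fell (camera adjusted p = 0.403), with a median of -0.04, a mean of 0.17 and an upward direction in camera. Of 6 Wnt targets 2 rose and 1 fell (camera adjusted p = 0.892).

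Markers of other cell types were mostly at low levels in both groups. The 5 lists of such markers each had fewer than 5 tested members and were not tested as sets. Of the epithelial and fibroblast markers 3 of 4 rose, with the keratin KRT8 moving from 8.39 ± 0.264 to 23.4 ± 0.168 CPM, KRT18 from 10.5 ± 0.767 to 23.1 ± 1.32 CPM and TAGLN from 10.5 ± 0.599 to 17.5 ± 1.36 CPM (SD, n = 3). The B cell genes PAX5 and CD79A rose, to 1.37 and 0.833 CPM, and the other 2 of 4 tested had no call. Of the 4 tested megakaryocyte genes 2 rose, or 1 adjusted over the list alone. ITGB3 went from 0.469 to 5.06 CPM, and GP1BA had an edgeR adjusted p of 0.0492 that did not hold when any of 5 libraries was left out, with an adjusted p of 0.062 to 0.355. The erythropoietin receptor EPOR, the erythroid gene tested, fell from 15.6 to 6.70 CPM, and IL7R, 1 of 2 tested T and NK cell genes, rose from 43.3 to 54.2 CPM and had the highest level of any of these markers in a library, 56.1 CPM.

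Some of these values are uncertain because reads could be shared. Without a stated strand setting, reads from overlapping genes cannot be told apart, and more than 10% of the exonic length of DDIT4, CEBPB, CCNE2, TAP2, BCL2L11, ICAM1, CIITA, HLA-B, LYZ, FCGR1A, NQO1, PRDX1, OSGIN1, ITGB3, KRT18 and TAGLN lay under exons of other genes. More than 10% of the 50-base stretches of ATF4, CIITA, FCGR1A, FTL, ITGB3, KRT18, LDHA, RPL4, RPL5 and TAP2 also occurred in other genes. For most of them the other genes were pseudogenes. ITGB3 shared 56.2% with AC068234.1, which overlaps it on the same strand. FCGR1A shared 46.6%, with FCGR1B and FCGR1CP. CIITA and TAP2 shared most with genes that overlap them on the same strand.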

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

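Setting aside 2 libraries, thinning and the GC and length correction were chosen after the data were seen. The ENO1 log2 fold change stayed between -5.02 and -4.94 in every setting run. The counts of higher and lower genes were within 1.5 times the main counts under every scaling, filter, tool and left-out library. Over these and the added settings they ranged from 3615 with DESeq2 to 4900 with library sizes alone for higher genes, and from 3608 with the 5 CPM filter to 5040 with the GC and length correction for lower genes. A threshold of 0.01 gave 3543 higher and 3808 lower genes. Requiring a 2-fold change reduced them to 953 higher and 521 lower genes by the construction of that threshold. Leaving out each library gave 3950 to 4228 higher and 4140 to 4515 lower genes, and setting aside control replicate 2 and knockdown replicate 3 together gave 4033 and 4303. No scaling moved the median of all genes by over 0.0532 on the log2 scale. Every scaling was relative, so a shift of all genes together could not be seen. Of the 8767 calls, 93.5% were kept with their direction under the GC and length correction and 4 reversed.

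Most of the named genes were chosen for a large change or a small adjusted p, so they were likely to keep their calls. Of all calls, 78.6% were kept with their direction under the 5 CPM filter, which tested fewer genes. Every other setting at the main threshold kept more, up to 99.7% under RLE scaling. The stricter thresholds were left out of this comparison and of the counts that follow. Of 143 named genes besides ENO1, 141 kept their direction and their side of the threshold in every setting that tested them. The exceptions were ENO3, which passed without knockdown replicate 2 and after thinning (edgeR adjusted p = 0.0351 and 0.0471), and GP1BA, whose adjusted p was 0.0617 to 0.355 in the settings where its call was lost; the cause was not tested. Of 30 lists, 15 kept their call in every setting that tested them, which leaves out DESeq2 for all lists and the 5 CPM filter for those with too few members left. Fry, which does not compare a list with other genes, called 12 lists higher and 16 lower, against 6 and 13 in camera. An estimated correlation left 4 and 9. The apoptosis list passed without a filter and in limma-voom (adjusted p = 0.0277 and 0.0474), and the heat shock list in those settings and with the 2 libraries set aside (0.00422, 0.00979 and 0.0393); the cause was not tested.

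The replicate numbers did not pair the libraries, with correlations of same-numbered deviations of -0.0741, -0.116 and -0.156 over 8004 genes, and no library correlated best with its own number. With the replicate number as a block, 4165 genes were higher and 4325 lower, and no list call changed. At these depths and replicate numbers, 46.0% of 1.2-fold changes were recovered in the simulation. The simulation changed far fewer genes than were called in the data, which made its adjustment stricter, so this share may be too low.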

Other observations

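The tests of the hairpin construct and of a general fall of growth genes, the GC and length correction and the thinning were chosen only after the results they bear on were seen, as was the choice to turn each split of the libraries so that the side with more controls stood for control. The lists of mitochondrially encoded mRNAs and replication-dependent histones below were also chosen then, and the genes named from them after their values were seen.

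Replication-dependent histone genes, which are normally transcribed in S phase, moved against the S phase list. Of 25 tested histone genes 22 rose and none fell, with a median log2 fold change of 1.49 (camera p = 8.03e-06; p = 0.0377 with an estimated correlation). H2AC6 rose from 4.68 to 33.9 CPM and H1-2 from 4.16 to 14.8 CPM, while most of the others stayed at a few CPM. H2BC12, the member with the highest level in both groups, rose by less than the list median. The mature mRNAs of these genes mostly lack poly(A) tails, so the counts may cover only a small part of them. The rise may therefore not reflect the full expression of these genes. Of the 13 mitochondrially encoded mRNAs 12 rose and none fell, with a median of 0.45 (camera p = 2.08e-07; p = 0.147 with an estimated correlation). MT-CYB and MT-ND1 rose by 0.67 and 0.65 on the log2 scale, although 22.1% of the 50-base stretches of MT-ND1 also occurred in another gene, whereas the nuclear genes of the respiratory chain had a median of 0.02.

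The first pattern weighed is that 59.9% of the tested genes differed. Correction for GC content and length kept 93.5% of the calls with their direction, which argues against those trends as the whole cause. Thinning to the smallest library kept 95.5%. Library totals differed little and were already scaled for, so thinning could hardly have removed most calls. Thinning therefore cannot test library size as a cause. The chromosome with the median farthest from 0 was chromosome 15 at 0.0613, which argues against a broad copy-number difference between the cultures. A response to the hairpin construct could not be told apart from an effect of the loss of ENO1. The columns name 1 hairpin, and whether the controls carried a control hairpin is not given. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split was the 1 with the most genes, with 4309 higher and 4458 lower against a highest other count of 0 in both directions. In edgeR the other splits had 80 to 137 genes at an unadjusted p below 0.05, and at the adjusted threshold at most 1 gene in DESeq2 and 0 in limma-voom. For lists the real split gave 6 higher and 13 lower against 6 and 12 in the other splits. Thus 2 of the 10 splits, the real one included, gave as many higher lists. Each other split mixed 2 libraries of one group with 1 of the other. That put the group difference into its spread and left part of that difference in its lists. Neither the gene counts nor the list counts of the splits therefore say anything of chance.

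The second pattern is the rise of all 19 tested interferon-stimulated genes. After the GC and length correction 98.4% of the list's median remained, which argues against that trend. A response to the hairpin construct and not to the loss of ENO1 cannot be told apart from an effect of the knockdown, since the columns name 1 hairpin and the labels describe the controls as untreated, while the letters NC in their names are not spelled out. Transcription of interferon genes in the knockdown cells may also contribute: none was above 0.184 CPM in any knockdown library, which would have counted against it under the bound set beforehand, but that bound was wrong because genes this close to the floor exclude nothing. IFNB1, singled out after its values were seen, had 7 counts over the knockdown libraries and 1 over the controls, a ratio of 8.18 (95% exact Poisson interval 1.05 to 369, counting error only), while all interferon genes together had 13 and 6 counts, a ratio of 2.53 (0.898 to 8.13), and IFNW1 and IFNL3 had 2 counts each in the controls and 0 in the knockdown libraries (33.0% of the 50-base stretches of IFNL3 also occurred in other genes).

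The third pattern is the fall of all cholesterol and fatty acid synthesis genes tested. After the GC and length correction the pooled median was 105% of its size before, which argues against that trend. A response to the hairpin construct cannot be told apart from an effect of the loss of ENO1 for the lipid genes either. The 27 lipid genes lay lower than the 36 cell-cycle genes by a median difference of -0.526 (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). The list medians had been seen before this contrast was chosen, and the permutation treats genes as independent. It therefore cannot test a general fall of growth genes, and shows only that the lipid genes fell by more than the cell-cycle genes. An excess of sterols, which would lower this pathway and turn on LXR targets, may be a candidate explanation: the 7 LXR targets tested had a median of -0.215, with 1 risen and 3 fallen, and ABCA1, a known LXR target seen before that list was made, had a log2 fold change of -2.33. The bound set beforehand, a median at or below 0 with more members fallen than risen, was met, but the members ran from -0.98 to 0.72, which is a 98.4% interval for the median if the members are independent, so that bound was too weak to exclude a rise and the explanation stays open.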
